A study of Homo sapiens with 24 samples.

How the data were processed

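RNA sequencing values of 24 libraries were used, 3 labelled control and 3 labelled CBX7 knockdown in each of 4 cell lines. Groups came from the genotype label of each sample. The titles contain CBX7 in both arms and differ by a hyphen, and the treatment label names an siRNA against CBX7 for controls too, whereas the protocol in the labels describes lentiviral short hairpin RNA against CBX7 or a control. Per the labels' protocols, libraries were made with a stranded total RNA kit and sequenced in pairs on an Illumina instrument. Whether the counting used strand is not given in the sources used here, so a gene and an overlapping or antisense gene cannot be told apart.

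The deposited gene table holds estimated counts of 19475 genes, which are the sums of the deposited estimated counts of 53016 transcripts. The authors also deposited FPKM per gene and TPM per transcript. HISAT2, StringTie and the genome build hg19 are named in the submitters' processing notes, without versions. Low estimated counts heap near multiples of 4. Of 39162 values from 1 to 25, 68.8% lie at a multiple of 4 or 1 above it, which are 12 of the 25 positions (48%). One fragment may thus have given several counts, but the files do not give fragment numbers, and total estimated counts per library are not taken as such. None of the 13 mitochondrially encoded genes was in the table used, so they were not analysed here.

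Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test), within each line on its 6 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are on the TMM-scaled library sizes unless stated to be of total counts. Those of the cell type markers and of the clotting and plasma protein genes are of total counts. The average effect over lines and the interaction (3 degrees of freedom) came from 1 model of all 24 libraries with 8 group means. Overlaps between lines were set against the number that independent lists give. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and adjusted over the lists of a line with at least 5 tested members. They were tested again with an estimated correlation and with fry, which tests whether a list moves and does not compare it with other genes. CBX7 transcripts were compared by exact permutation tests. The trend of log2 fold change with transcript length, 3' UTR length and GC content (GENCODE release 29) was fitted with natural splines of 4 degrees of freedom on the genes outside a list. The fitted value that was subtracted holds the mean level of those genes, which need not be 0, as well as the trend. For ribosomal proteins this fit was set down before its result, but for a pattern already seen in the data. For other lists it was chosen after seeing the data.

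The groups, designs, 42 gene lists, naming rule and other settings to be tried were fixed before the data were examined. The naming rule took CBX7. Per line it took the 8 highest and 8 lowest log2 fold changes among called genes whose groups did not overlap and whose higher group had at least 5 CPM, leaving out clone, locus, antisense, small RNA and open reading frame names. It also took the 2 highest and 2 lowest called members of each list past its test, and of the Polycomb repressive complex 1, CDK inhibitor and HOX lists in any case. Across lines it took at most 10 genes per direction called the same way in all 4 lines. F9, the other clotting and plasma protein genes and single fibroblast genes were chosen after their values were seen.

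The settings chosen beforehand were DESeq2 1.42.0 size factors and its Wald test, no filter, a filter of 1 CPM in 3 libraries, a replicate block, and all 24 libraries in one fit. Others were limma on log2(FPKM + 1) or log2(FPKM + 0.1) of genes with FPKM of at least 1 in 3 libraries, limma without that filter, a 2-fold limit, an adjusted p under 0.01, and leaving out each library. Counts divided by 4, K562 control replicate 3 alone and A549 knockdown replicate 1 alone were added after seeing the data. A lone library is assumed there to vary like the libraries of the other arm. Over 24 pairs of replicates the chi-square per degree of freedom on counts divided by 4 was 8.60 to 72.7, so no replicate repeated the values of another. As the counts per fragment are not known, repeated sequencing of the same library is not excluded.

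The tests were tried on simulated counts, 5 simulations per line with 200 changed genes each. With each gene's own spread, 83.6% of genes changed 2-fold were recovered among 14980 genes for A549, 81.2% among 14621 for H1299, 77.9% among 13876 for K562 and 70.8% among 14259 for THP-1, and for 1.5-fold changes 65.1%, 60.0%, 59.4% and 16.7%. The share of false calls was then 8.82%, 10.1%, 9.76% and 7.10%, above the nominal level. With a smooth spread it was 4.32%, 3.79%, 4.51% and 4.83%. For the 24-library model of 16797 genes, 85% of simulated average effects and 67% of simulated interactions were recovered. Far more genes were called in the data, at least 1458 in each line, so recovery and false shares may differ there.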

Results

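RNA was sequenced from 4 human cell lines to ask what follows when CBX7 is lowered, the purpose stated by the title of the series. CBX7 is a chromodomain subunit of Polycomb repressive complex 1, which keeps developmental genes silent. A549 is a lung adenocarcinoma line, H1299 a non-small-cell lung carcinoma line that lacks p53, K562 a chronic myeloid leukaemia line with erythroid features and THP-1 an acute monocytic leukaemia line. Each line had 3 libraries labelled CBX7 knockdown and 3 labelled control, 24 in all. Total estimated counts per library ran from 71.1 M to 117 M in A549, 81.9 M to 132.5 M in H1299, 75.3 M to 114.3 M in K562 and 75.9 M to 108.9 M in THP-1. The number of sequenced fragments behind these estimates is not known. Between 14340 and 15844 genes had a count above 0, and the most abundant gene took at most 2.03% of a library. The labels do not say that the replicates were separate cultures. The p-values of single genes and transcripts thus measure only the spread between these libraries, which may be technical. Those of camera, which compares a list with other genes at a preset correlation, also rest on the spread between genes. With an estimated correlation 54 of 60 list calls were lost.

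The libraries carried the markers of their lines, apart from alveolar and airway genes in H1299. The median level over 39 erythroid genes was 86.9 to 155.8 CPM (estimated counts scaled to a common library size) in K562 libraries and at most 0.503 CPM in the other lines. That over 44 monocyte genes was 33.5 to 40.3 CPM in THP-1 and at most 0.430 CPM elsewhere. Granule protein genes of early myeloid cells had medians of 3.18 to 4.86 CPM in THP-1. Epithelial genes had medians of 13.9 to 15.9 CPM in A549 and 3.03 to 4.92 CPM in H1299, and alveolar and airway genes 0.376 to 1.63 CPM in A549. Megakaryocyte genes reached 3.18 CPM in K562, neural genes 1.39 CPM in H1299 and lymphoid genes 0.20 CPM in K562, the highest medians of those lists in any library.

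CBX7 itself went against the labels in all 4 lines. Its level was 5.998 ± 0.44 CPM in A549 libraries labelled control and 50.9 ± 1.36 CPM in those labelled knockdown (mean ± SD, n = 3 each, as for all CPM below), a log2 fold change of 3.08 ± 0.07 (SE). In H1299 it was 32.2 ± 0.91 and 396.1 ± 12.6 CPM (3.62 ± 0.04), in K562 13.8 ± 0.94 and 39.2 ± 0.41 CPM (1.51 ± 0.06) and in THP-1 15.8 ± 1.73 and 36.4 ± 4.08 CPM (1.20 ± 0.13). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 3.18e-12 in A549, 2.02e-13 in H1299, 3.96e-08 in K562 and 0.00144 in THP-1, and all 3 libraries labelled knockdown lay above all 3 labelled control in each line. The estimated counts behind these values were 579 to 736 against 3826 to 4689 in A549, 3622 to 4092 against 34911 to 38367 in H1299, 981 to 1499 against 3255 to 3878 in K562 and 1402 to 1560 against 2829 to 3527 in THP-1. Higher and lower below always mean higher and lower in the libraries labelled knockdown, which were the libraries with more CBX7.

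**Figure D1:**
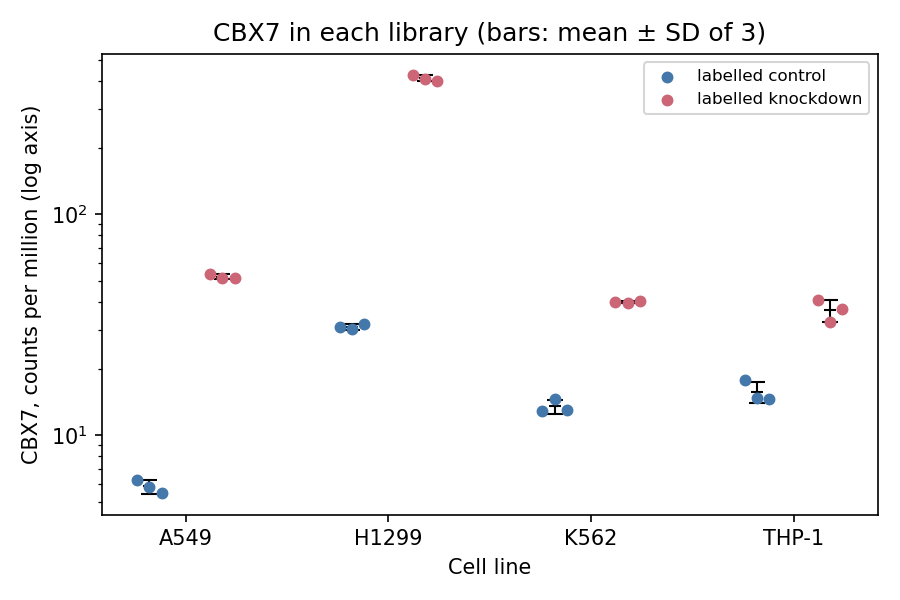
CBX7 in each of the 24 libraries, in CPM of the library's total estimated counts on a log axis, by cell line. Points are libraries labelled control or knockdown and black bars are the mean ± SD of 3 libraries; in H1299 the libraries labelled knockdown lie between 401 and 426.1 CPM and those labelled control between 30.1 and 31.9 CPM, and in THP-1 between 32.4 and 40.7 and between 14.6 and 17.7 CPM.

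By group means the transcript NM_175709 carried most of the CBX7 signal. Its share was 44.4% in K562 control replicate 1 and 47.3% and 44.3% in K562 knockdown replicates 2 and 3. It was 44.7% in THP-1 control replicate 1. In H1299 its level was 11.6 TPM in the libraries labelled control and 225.6 TPM in those labelled knockdown, and in A549 2.68 and 26.9 TPM. Levels were 4.34 and 12.95 TPM in K562 and 5.48 and 12.2 TPM in THP-1. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 in each line, the smallest it can give. The share of NM_175709 among CBX7 transcripts was 77.2 ± 5.97% and 89.5 ± 0.85% in H1299 (exact permutation p = 0.1) and 74.7 ± 13.2% and 83.3 ± 1.53% in A549 (exact p = 0.3). It was 57.7 ± 12.8% and 60.1 ± 24.8% in K562 (exact p = 0.9) and 60.6 ± 13.8% and 56.0 ± 2.86% in THP-1 (exact p = 0.6).

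In A549, the genes of DNA replication and cell division were lower in the libraries labelled knockdown. Of 46 S phase genes, 44 fell and 2 did not pass the test (46 fell when adjusted over the list alone), with a median log2 fold change of -1.33. RRM2, a subunit of ribonucleotide reductase, went from 186.2 ± 4.20 to 29.9 ± 1.42 CPM (log2 fold change -2.64 ± 0.04), and E2F8, a repressor in the E2F family, changed by -2.25 ± 0.09. PCNA, the sliding clamp of DNA polymerase, changed least among the examples at -0.50 ± 0.03. Of 55 genes of G2 and mitosis, 54 fell (54 adjusted over the list alone), median -1.76, among them BIRC5 (140.9 ± 2.19 to 30.1 ± 1.29 CPM) and CDC25C, the phosphatase that activates mitotic CDK1 (-2.26 ± 0.09). TK1, thymidine kinase (-2.45 ± 0.05), and KIF20A, a mitotic kinesin (-2.34 ± 0.04), were among the 8 largest decreases of the line in genes with at least 5 CPM in the higher group. The camera set test gave adjusted p = 3.35e-24 for S phase and 6.21e-32 for G2 and mitosis, and both calls held with an estimated correlation (adjusted p = 0.0354 and 0.0175).

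Among 35 targets of p53, 24 rose and 4 fell (24 and 4 adjusted over the list alone), median 0.42. CDKN1A, the CDK inhibitor p21, went from 120.6 ± 6.34 to 260.4 ± 3.16 CPM (1.11 ± 0.04). RRM2B, the p53-induced ribonucleotide reductase subunit, went from 26.5 ± 5.32 to 115.6 ± 5.14 CPM (2.13 ± 0.17), while SESN2, a stress-induced inhibitor of mTORC1 signalling, fell (-0.68 ± 0.06). Ribosome biogenesis genes moved down, with 1 higher and 30 lower of 36 (1 and 31 adjusted over the list alone), median -0.30. NOP56, a snoRNP core protein, changed by -0.75 ± 0.03. The camera adjusted p was 1.02e-06 for p53 targets and 1.45e-07 for ribosome biogenesis, and both held with an estimated correlation (adjusted p = 0.0362 for each). Among subunits of Polycomb repressive complex 2, 1 rose and 8 fell of 13 (1 and 8 adjusted over the list alone). EZH2, its catalytic subunit, went from 68.2 ± 0.48 to 23.5 ± 1.22 CPM. That list had an adjusted p = 0.0374, with adjusted p = 0.301 with an estimated correlation, and missed the threshold without knockdown replicate 3 (adjusted p = 0.0535).

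Mesenchymal and extracellular matrix genes were higher in A549 libraries labelled knockdown, with 23 higher and 3 lower of 36 (25 and 3 adjusted over the list alone), median 0.75 (camera adjusted p = 2.63e-05, but adjusted p = 0.263 with an estimated correlation). Their libraries differed widely. COL1A2, a chain of type I collagen, was at 13.8, 74.7 and 85.0 CPM of total counts in labelled-knockdown replicates 1, 2 and 3, against 0, 0.0489 and 0 CPM in the controls. Its call ended without control replicate 2 (adjusted p = 0.0722). COL6A3 went from 0.426 ± 0.18 to 35.3 ± 23.2 CPM and IGFBP5, a secreted binding protein, from 7.15 ± 0.74 to 142 ± 79.9 CPM (4.31 ± 0.66). VIM, vimentin, fell from 996.1 ± 0.86 to 742.3 ± 11.2 CPM (-0.42 ± 0.02) and S100A4 by 0.77 ± 0.03 on the log2 scale. Values of 5 matrix genes, chosen after their values were seen, were compared in the other lines. In K562 COL6A3 (5.15 ± 1.14 to 13.8 ± 3.89 CPM, adjusted p = 0.00464) and DCN (0.852 ± 0.38 to 4.25 ± 2.13 CPM, adjusted p = 0.00693) rose, but neither passed against control replicate 3 alone (adjusted p = 0.0987 and 0.132). COL1A1 went from 1.24 ± 1.34 to 13.3 ± 7.67 CPM in K562 (adjusted p = 0.0463), a call kept without control replicate 3 and ended without any other single library (0.0795 to 0.125). There COL1A2 (0.73 ± 0.50) and IGFBP5 (2.70 ± 0.95) did not pass (adjusted p = 0.283 and 0.0752). Knockdown replicate 3 held the highest level of all 5 genes among the K562 libraries. In H1299 COL1A2 rose from 0.0760 ± 0.07 to 1.29 ± 0.33 CPM (adjusted p = 0.00256). COL1A1 (1.07 ± 0.16), COL6A3 (5.49 ± 1.00) and IGFBP5 (5.33 ± 1.25) passed there as well. IGFBP5 did not pass without knockdown replicates 1, 2 or 3 (edgeR adjusted p = 0.0570, 0.0591 and 0.0563). DCN did not pass there (0.43 ± 0.28, adjusted p = 0.183). COL6A3 and IGFBP5 were near the floor, at most at 0.0332 and 0.199 CPM of total counts in H1299 controls. In H1299 libraries labelled knockdown they were at 0.376 to 0.964 and 2.76 to 3.14 CPM. With all 24 libraries in one edgeR fit, COL1A1 in H1299 (adjusted p = 0.179) and COL6A3 in K562 (0.0521) did not pass. In H1299 COL6A3 missed under limma on log2(FPKM + 1) with no filter (adjusted p = 0.0530). IGFBP5 missed there with the replicate block in edgeR (adjusted p = 0.0709). In THP-1 COL1A1, COL1A2, COL6A3, DCN and IGFBP5 did not pass (edgeR adjusted p = 0.599, 0.713, 0.775, 0.426 and 0.740). There such traces varied between controls, with IGFBP5 at 3.60, 0.0758 and 2.10 CPM of total counts in control replicates 1, 2 and 3. It was at 2.47 to 3.45 CPM in the THP-1 libraries labelled knockdown. The mesenchymal list had 13 higher and 4 lower of 30 in K562 (13 and 4 adjusted over the list alone) and 12 and 13 of 36 in H1299 (12 and 13), with camera adjusted p = 0.0924 and 0.860. In A549, against the controls, knockdown replicate 1 alone, a comparison chosen after seeing the data in which the lone library is assumed to vary like the controls, kept the call of the list.

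Metabolic lists moved by smaller amounts in A549. Of 34 NRF2 targets, 4 rose and 23 fell (5 and 23 adjusted over the list alone), with AKR1B10, an aldo-keto reductase, at 5249 ± 36.0 and 2677 ± 41.3 CPM and HMOX1, heme oxygenase, higher (0.70 ± 0.04). Of 24 cholesterol synthesis genes, 3 rose and 15 fell (3 and 16 adjusted over the list alone), including EBP (-1.04 ± 0.07). Of 17 fatty acid synthesis genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone), including SREBF1, the transcription factor of lipid synthesis, at 345 ± 7.54 and 159.9 ± 5.02 CPM. Nuclear genes of the respiratory chain had 33 lower of 48 (33 adjusted over the list alone), median -0.21. Ribosomal protein genes, whose counts may share reads with pseudogenes, had 54 higher and 3 lower of 75 (55 and 3 adjusted over the list alone), median 0.14. By camera the adjusted p was 0.000195 for NRF2 targets, 0.00126 for cholesterol, 0.0202 for fatty acids, 1.57e-05 for the respiratory chain and 1.63e-09 for ribosomal proteins. With an estimated correlation these calls were lost, at adjusted p = 0.0601, 0.0770, 0.136, 0.0601 and 0.102 in the same order.

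In all, 4069 genes were higher and 4255 lower in A549 among 14980 tested (edgeR quasi-likelihood, adjusted p under 0.05), 747 and 463 of them at least 2-fold. The 2 groups did not overlap for 63.7% of genes, where chance gives 10%. Under limma on FPKM with no filter the calls were 4923 higher and 3335 lower, and with all 24 libraries in one fit 2914 higher and 2750 lower. All 3 A549 control libraries held reads of the clotting factor gene F9, at 0.470 to 0.624 CPM, and no library labelled knockdown did. F11 reads likewise were found in the controls alone. HRG and SERPIND1, which encode other plasma proteins, were at 0.743 CPM or more and 1.02 CPM or more in the controls and at most at 0.1125 and 0.162 CPM in the libraries labelled knockdown. Other genes of this kind did not follow that split. PLG was at 1.66 to 1.79 CPM in the controls and 1.74 to 2.06 CPM in the libraries labelled knockdown, F2 at 5.597 to 6.10 and 3.93 to 5.43 CPM, and F5 at 34.2 to 35.9 and 69.7 to 73.5 CPM. Since F9 and F11 reads coincide with the labels, a difference between library sets cannot be told apart from the label in this line.

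In H1299, genes of the ribosome and of mitochondrial respiration were lower in the libraries labelled knockdown. Of 75 ribosomal protein genes 74 fell (74 adjusted over the list alone), median -0.93. RPLP2, a protein of the ribosomal stalk, went from 656 ± 30 to 272.7 ± 10.1 CPM (-1.27 ± 0.04), and RPL4 from 3245 ± 38.8 to 2149 ± 34.6 CPM (-0.59 ± 0.02). Of 48 nuclear respiratory chain genes 2 rose and 45 fell (2 and 45 adjusted over the list alone), median -0.64, with NDUFV1, a core subunit of complex I, at 121.1 ± 3.01 and 59.3 ± 2.24 CPM and NDUFS1 higher (0.28 ± 0.03). Ribosome biogenesis genes had 5 higher and 26 lower of 36 (6 and 26 adjusted over the list alone), median -0.82. FBL, the rRNA methyltransferase fibrillarin, went from 917.9 ± 16.5 to 322.8 ± 4.45 CPM (-1.51 ± 0.03). Adjusted p from camera was 4.18e-22, 1.38e-10 and 0.000157 for these lists. They became adjusted p = 0.298, 0.321 and 0.298 with an estimated correlation. Across genes, which are not independent replicates, the H1299 log2 fold change rose with transcript length (Spearman 0.57, against -0.09 to 0.09 in the other lines). Length, 3' UTR length and GC content together took 28.3% of its variance over genes other than ribosomal proteins, against 0.880 to 1.66% in the other lines. With that trend of other genes removed, the median was -0.59 for ribosomal proteins, -0.28 for the respiratory chain and -0.66 for ribosome biogenesis.

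Heat shock proteins were also lower in H1299, with 2 higher and 15 lower of 21 (2 and 15 adjusted over the list alone), median -0.44. HSPA1A and HSPA1B, near-identical copies whose counts are uncertain singly, changed by -1.82 ± 0.03 and -1.81 ± 0.03. Of 46 S phase genes 5 rose and 32 fell (6 and 32 adjusted over the list alone), with CDC45, a replication helicase factor, lower (-1.03 ± 0.05) and CASP8AP2 higher (1.06 ± 0.05). Of 55 genes of G2 and mitosis 14 rose and 33 fell (14 and 33 adjusted over the list alone), with UBE2C, a mitotic ubiquitin enzyme, lower (-1.32 ± 0.04) and CENPE, a kinetochore motor, higher (0.73 ± 0.07). The set test by camera gave adjusted p = 0.000860, 0.000408 and 0.0230 for the 3 lists. These moved to adjusted p = 0.298, 0.298 and 0.428 with an estimated correlation. Within the lists the change rose with transcript length as well (Spearman 0.47, 0.70 and 0.81 across genes, in this order). With the trend of other genes in length, 3' UTR length and GC content removed, the median of heat shock proteins was -0.41, that of S phase genes went from -0.35 to -0.48 and that of G2 and mitosis genes from -0.27 to -0.46.

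Amino acid stress and fatty acid genes were higher in H1299. Of 31 genes of the ATF4 response 20 rose and 5 fell (20 and 5 adjusted over the list alone), median 0.40. SLC7A11, the cystine transporter, went from 5.56 ± 0.57 to 39.4 ± 1.09 CPM (2.83 ± 0.08), and SHMT2, a mitochondrial serine enzyme, fell (-0.53 ± 0.04). Of 17 fatty acid synthesis genes 12 rose and 2 fell (12 and 2 adjusted over the list alone), median 0.30, with SCD, the stearoyl-CoA desaturase, at 2204 ± 16.6 and 4529 ± 24.6 CPM. The camera adjusted p was 0.0141 and 0.0133. With an estimated correlation these became adjusted p = 0.298 for each. With the trend in length and GC content removed, the ATF4 median was 0.49 and the fatty acid median 0.03. ID1 and ID3, inhibitors of basic helix-loop-helix factors, were among the 8 largest decreases, ID1 from 292.4 ± 4.07 to 49.6 ± 3.56 CPM (-2.56 ± 0.05) and ID3 by -2.33 ± 0.03, together with ANKRD1 (-3.36 ± 0.14). NBEAL1 went from 2.27 ± 0.07 to 35.1 ± 3.16 CPM (3.95 ± 0.08) and TTBK2, a tau tubulin kinase, from 3.59 ± 0.80 to 35.5 ± 0.31 CPM. ZBED6 and KIAA0754, which lie inside ZC3H11A and MACF1, changed by 4.87 ± 0.28 and 4.46 ± 0.12, but their reads cannot be told from those of the host genes here.

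In all, 4888 genes were higher and 5187 lower in H1299 among 14621 tested (edgeR quasi-likelihood, adjusted p under 0.05), 1303 and 746 of them at least 2-fold, with no overlap of the groups for 74.5% of genes against 10% by chance. With an estimated correlation 0 of 40 lists passed, while 6 had an unadjusted p under 0.05 and fry called 35. All 3 H1299 control libraries and no library labelled knockdown held F9 reads (0.362 to 0.515 CPM in the controls). Reads of F11 were found in knockdown replicates 1 and 3 (0.0610 and 0.1045 CPM), below the 0.343 to 0.507 CPM of the controls, and library set and label cannot be told apart in this line either.

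In K562, the amino acid response was the largest list change in the libraries labelled knockdown. Of 32 genes of the ATF4 response 30 rose (31 adjusted over the list alone), median 2.16. CHAC1, a glutathione-degrading enzyme, went from 1.38 ± 0.10 to 32.4 ± 1.82 CPM (4.55 ± 0.09). ALDH1L2, a mitochondrial folate enzyme, went from 7.53 ± 0.81 to 141.8 ± 5.06 CPM (4.23 ± 0.08), and SLC3A2, a chain of amino acid transporters, rose by less (0.94 ± 0.04). ASS1, argininosuccinate synthase, was among the 8 largest increases, from 1.36 ± 0.16 to 57.9 ± 0.79 CPM (5.42 ± 0.09), and SLC6A9, a glycine transporter, went from 5.01 ± 0.82 to 79.1 ± 2.22 CPM. By camera the adjusted p was 1.67e-20 for the list, which held with an estimated correlation (adjusted p = 0.0151).

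Erythroid genes were mostly higher in K562, with 26 higher and 6 lower of 37 (26 and 6 adjusted over the list alone), median 0.59. SLC4A1, the band 3 anion exchanger, went from 1.95 ± 0.40 to 19.8 ± 0.99 CPM (3.34 ± 0.14), while TFRC, the transferrin receptor, fell from 1092 ± 35.1 to 478.8 ± 9.52 CPM (-1.19 ± 0.04). Cholesterol synthesis genes had 1 higher and 18 lower of 24 (1 and 18 adjusted over the list alone), median -0.89, with INSIG1, a sterol sensor, at 362.1 ± 6.40 and 123.2 ± 6.72 CPM and LSS, lanosterol synthase, at 353.4 ± 18.9 and 135.2 ± 1.77 CPM. Heat shock proteins had 1 higher and 17 lower of 21 (1 and 17 adjusted over the list alone), median -0.57, with HSPA8 at 3536 ± 154.7 and 1400 ± 31.7 CPM. Ribosome biogenesis genes had 2 higher and 26 lower of 36 (2 and 26 adjusted over the list alone), with UTP20 lower (-1.07 ± 0.04). Adjusted p from camera was 3.03e-05, 3.10e-08, 1.51e-08 and 4.05e-06 in this order. They became adjusted p = 0.351, 0.0555, 0.166 and 0.0555 with an estimated correlation.

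Targets of NF-kappaB had 3 higher and 17 lower of 30 in K562 (3 and 17 adjusted over the list alone), median -0.67. CXCL8, the chemokine interleukin 8, went from 18.7 ± 1.25 to 2.50 ± 0.39 CPM, and TNFAIP3, an inhibitor of the pathway, rose (1.06 ± 0.08). CCL3 was at 0.474 ± 0.06 CPM in the controls and at 0 in all libraries labelled knockdown. Hypoxia and glycolysis genes had 8 higher and 21 lower of 34 (8 and 21 adjusted over the list alone), median -0.38, with PKM, pyruvate kinase, at 821.2 ± 11.1 and 277.9 ± 2.74 CPM and VEGFA higher (1.57 ± 0.05). Nuclear respiratory chain genes had 3 higher and 24 lower of 48 (3 and 24 adjusted over the list alone), median -0.17. Ribosomal protein genes had 26 higher and 5 lower of 75 (25 and 4 adjusted over the list alone), median 0.10. The set test by camera gave adjusted p = 0.000373, 0.00443, 0.000669 and 0.0113. These moved to adjusted p = 0.102, 0.149, 0.351 and 0.581 with an estimated correlation. With the trend in length, 3' UTR length and GC content removed, the ribosomal median turned to -0.05 (quartiles -0.15 to 0.01) and the respiratory median was -0.31. The fit took 0.880% of the variance over genes other than ribosomal proteins. All lists so treated moved down in K562, ATF4 response genes from 2.16 to 1.98 too. The subtracted value holds the mean level of other genes, so these moves are not assigned to length or GC content. CD24, a surface glycoprotein (142 ± 7.35 to 22.9 ± 1.72 CPM), and ITGAX, an integrin chain (43.0 ± 1.32 to 6.53 ± 0.51 CPM), were among the 8 largest decreases.

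In all, 4012 genes were higher and 3822 lower in K562 among 13876 tested (edgeR quasi-likelihood, adjusted p under 0.05), 1080 and 351 of them at least 2-fold, with no overlap of the groups for 65.6% of genes against 10% by chance. F9 reads were present in control replicates 1 and 2 and absent from control replicate 3 and the libraries labelled knockdown. SERPIND1 was at 1.435 and 1.40 CPM in control replicates 1 and 2, at 0.292 CPM in control replicate 3 and at most at 0.183 CPM in the libraries labelled knockdown. Against control replicate 3 alone, a comparison chosen after seeing the data, 3203 genes were higher and 3034 lower, and the log2 fold change of CBX7 was 1.56. The spread there comes from the 3 libraries labelled knockdown, and the lone control is assumed to vary like them. All 12 list calls held, and 14 of 93 calls of named genes ended.

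In THP-1, genes induced by type I interferon were higher in the libraries labelled knockdown. Of 47 genes 36 rose (40 adjusted over the list alone), median 1.06. IFIT3, an antiviral protein, went from 3.34 ± 0.12 to 31.8 ± 2.50 CPM (3.25 ± 0.11) and IFI44L from 1.62 ± 0.25 to 18.6 ± 4.07 CPM (3.52 ± 0.21). Counts of IFIT1 (3.12 ± 0.14) and its paralogs may share reads. The camera adjusted p was 1.12e-30, which held with an estimated correlation (adjusted p = 0.00566).

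In THP-1 5 lists of stress, sterol and signalling genes passed the set test upwards, a call each lost with an estimated correlation. Of 31 genes of the ATF4 response 19 rose (24 adjusted over the list alone), median 0.54, SLC7A11 going from 19.5 ± 1.5 to 154.1 ± 33.3 CPM (2.99 ± 0.17). Of 23 cholesterol synthesis genes 12 rose and 1 fell (19 and 1 adjusted over the list alone), median 0.52. IDI1, an isoprenoid isomerase, was the member that fell (-0.78 ± 0.09), and HMGCS1, a synthase of the mevalonate pathway, rose from 97.6 ± 23.1 to 211.5 ± 17.2 CPM, a call that ended without knockdown replicate 2 (adjusted p = 0.0604). NRF2 targets had 15 higher of 34 (19 adjusted over the list alone), with AKR1C2, an aldo-keto reductase with close paralogs, at 1.07 ± 0.26 and 11.9 ± 1.26 CPM. Endoplasmic reticulum chaperones had 9 higher of 24 (13 adjusted over the list alone), among them DNAJB9 (0.83 ± 0.12) and HERPUD1 (0.74 ± 0.09). Feedback regulators of ERK signalling had 6 higher of 18 (9 higher and 1 lower adjusted over the list alone), among them SPRY4 (1.99 ± 0.24). By camera the adjusted p was 5.75e-14, 5.38e-10, 7.39e-10, 1.89e-06 and 3.29e-06 for the 5 lists. With an estimated correlation these became adjusted p = 0.0588, 0.0588, 0.0627, 0.0825 and 0.0588.

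CDKN1A also rose in THP-1, from 32.0 ± 2.21 to 79.5 ± 5.60 CPM (1.31 ± 0.10), and KIT, the stem cell factor receptor, fell from 36.8 ± 2.20 to 5.15 ± 0.32 CPM (-2.84 ± 0.11). FAP, a membrane protease of activated fibroblasts, went from 0.260 ± 0.09 to 7.85 ± 0.46 CPM and FABP4, a fatty acid carrier, from 1.28 ± 0.47 to 14.5 ± 4.40 CPM. GAPT (-1.98 ± 0.12) and CFP, the complement factor properdin (-1.87 ± 0.12), were among the 8 largest decreases. Of 46 S phase genes 5 fell (8 adjusted over the list alone), median -0.16 (camera adjusted p = 3.22e-05, adjusted p = 0.190 with an estimated correlation). Of 75 ribosomal protein genes 1 passed the test over all genes, and their median was -0.18 (camera adjusted p = 8.56e-06, adjusted p = 0.580 with an estimated correlation). With the trend in length, 3' UTR length and GC content removed, the S phase median was -0.25 and the ribosomal median -0.33. The fit took 1.66% of the variance over genes other than ribosomal proteins. As the mean level of other genes was removed with the trend, these moves are not assigned to length or GC content.

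In all, 898 genes were higher and 560 lower in THP-1 among 14259 tested (edgeR quasi-likelihood, adjusted p under 0.05), 343 and 70 of them at least 2-fold, with no overlap of the groups for 35.6% of genes against 10% by chance. The counts moved with single libraries, to 1738 higher and 1586 lower without knockdown replicate 2, 540 and 318 without knockdown replicate 1, 533 and 311 without knockdown replicate 3, and 434 and 187, 393 and 167, and 392 and 191 without control replicates 1, 2 and 3. Knockdown replicate 2 stood apart from replicates 1 and 3, with median log2 differences of 0.48 in ribosomal protein genes and 0.46 in respiratory chain genes. F9 reads were found in no THP-1 library.

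**Figure D2:**
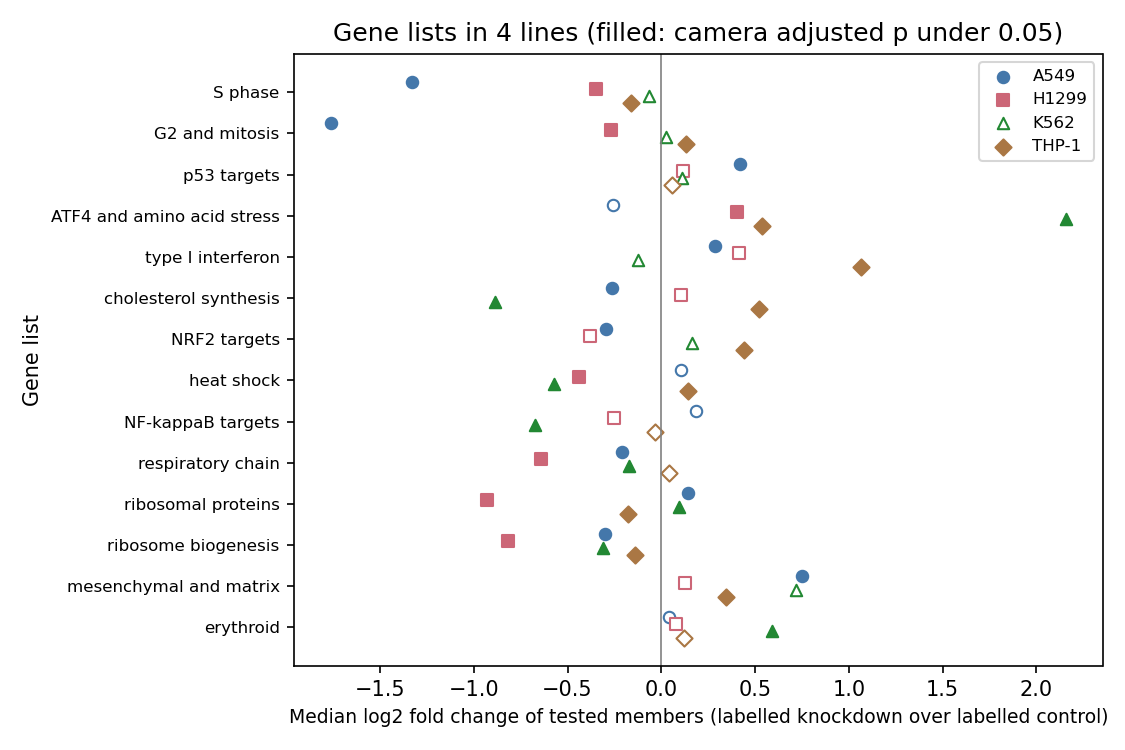
Median log2 fold change (libraries labelled knockdown over labelled control) of the tested members of 14 gene lists in the 4 cell lines, filled where the camera adjusted p was under 0.05. S phase and G2 and mitosis genes lie lowest in A549 (-1.33 and -1.76), ribosomal proteins in H1299 (-0.93), ATF4 response genes highest in K562 (2.16) and interferon genes highest in THP-1 (1.06).

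The lists tied most closely to CBX7 showed no direction common to all 4 lines. Log2 fold changes in H1299 rose with transcript length, a trend not removed from the HOX, Polycomb repressive complex 1 or CDK inhibitor lists. HOX genes, classical Polycomb targets, had 14 higher and 1 lower of 36 in A549 (14 and 1 adjusted over the list alone), 4 and 18 of 33 in H1299 (4 and 18) and 7 and 6 of 26 in K562 (7 and 6). For these lines the HOX medians were 0.24, -0.30 and 0.24, and camera gave adjusted p = 0.0547, 0.141 and 0.697. In THP-1 16 were tested, with a median of 0.27 (adjusted p = 0.0795). In A549 HOXD8 rose (1.06 ± 0.22) and HOXB7 was the member that fell (-0.36 ± 0.06). HOXD3 was higher there too (1.42 ± 0.53), a call that ended without control replicates 1 or 2 or knockdown replicates 1 or 3 (adjusted p = 0.0986, 0.0962, 0.128 and 0.0715). HOXD3 (1.58 ± 0.46) and HOXA13 (1.23 ± 0.30) rose in H1299, while HOXB5 fell (-0.95 ± 0.10). In K562 HOXB13 went from 0.193 ± 0.11 to 1.39 ± 0.10 CPM (2.83 ± 0.45) and HOXB6 from 20.2 ± 0.14 to 9.55 ± 0.13 CPM. Other subunits of Polycomb repressive complex 1 had 2 higher and 9 lower of 21 in A549, 11 and 3 in H1299, 3 and 9 in K562 and 1 and 1 in THP-1, the same numbers adjusted over the list alone. BCOR (1.30 ± 0.06) and RYBP (1.01 ± 0.05) were higher in H1299 and CBX2 was lower in K562 (-0.66 ± 0.06). Camera gave adjusted p = 0.325, 0.186, 0.189 and 0.838. CDK inhibitors had 1 higher and 3 lower of 6 in A549, 2 and 4 of 8 in H1299 and 2 and 2 of 6 in K562, the same numbers adjusted over the list alone (camera adjusted p = 0.381, 0.589 and 0.976). In THP-1, 1 of 6 rose (2 adjusted over the list alone), at camera adjusted p = 0.0392, with adjusted p = 0.403 with an estimated correlation and 0.2045 without knockdown replicate 2. CDKN2A, the Polycomb target that encodes p16 and ARF, was measured in H1299 at 279.4 ± 42.3 CPM in the controls and 127.2 ± 7.12 CPM in the libraries labelled knockdown (-1.14 ± 0.14), and its neighbour CDKN2B rose (0.78 ± 0.05). CDKN1A was higher in all 4 lines, by 1.11 ± 0.04 in A549, 0.27 ± 0.04 in H1299, 0.53 ± 0.07 in K562 and 1.31 ± 0.10 in THP-1.

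Among 12191 genes tested in all lines, 67 were called higher in all 4, where independent lists would give 17.3, and 39 were called lower in all 4, where they would give 17.2. Calls in exactly 3 lines were made for 740 genes that were higher and 1035 that were lower. Part of the excess over independent lists may come from a difference between library sets shared by lines, which was not tested. F9 reads were found in controls of A549, H1299 and K562, in no library labelled knockdown and in no THP-1 library. A call in all 4 needs one in THP-1, where 1458 genes were called. In simulations of that line with 200 changed genes, 16.7% of 1.5-fold changes were recovered. MRAS, a small GTPase of the RAS family, had log2 fold changes of 0.69 in A549, 0.67 in H1299, 1.30 in K562 and 0.69 in THP-1 (mean 0.86 ± 0.03, SE). ARHGAP33, a GTPase-activating protein, had -2.11, -1.11, -0.54 and -1.07 (mean -1.18 ± 0.06). GBP1, an interferon-induced GTPase, went from 1.21 to 3.38 CPM in A549, 5.75 to 10.8 CPM in H1299 and 0.248 to 1.83 CPM in THP-1, and from 0 to 0.279 CPM in K562. RTEL1, a DNA helicase at telomeres, had log2 fold changes of -0.66, -0.79, -0.75 and -0.72 (mean -0.70 ± 0.05). Of the 20 named genes, 14, RTEL1 included, lost their THP-1 call when a library was left out. They were 13 without control replicate 1, 12 without control replicate 2, 14 without control replicate 3, 9 without knockdown replicate 1 and 12 without knockdown replicate 3, at adjusted p of 0.0554 to 0.150 (edgeR quasi-likelihood, Benjamini-Hochberg).

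With all 24 libraries in one model, 4852 genes were higher and 3568 lower on average over the lines among 16797 tested. For 10898 genes, or 64.9%, the effect differed between lines (3-degree F test of the interaction), 7279 genes being in both sets. The trend of H1299 log2 fold changes with transcript length (Spearman 0.57), not seen at that size in the other lines, was not removed. It may add to the count of differing genes. Pairs of lines shared calls to different degrees. A549 and H1299 had 1601 genes higher in both, against 1280 for independent lists, 2166 lower in both, against 1517, and 2290 in opposite directions, against 2786. In the same order, H1299 and K562 had 1376, 1785 and 2509, against 1260, 1402 and 2666. A549 and K562 had 1361, 1639 and 1663, against 988.2, 1153 and 2144. A549 and THP-1 had 364, 125 and 324, against 217.1, 155.1 and 383.9. H1299 and THP-1 had 323, 241 and 334, against 270.3, 187.7 and 467.7. K562 and THP-1 had 314, 168 and 300, against 211.5, 142.7 and 354.8. A difference between library sets shared by lines may add to these overlaps, which was not tested. Across genes, which are not independent replicates, the Pearson correlation of log2 fold changes over the 6 pairs ran from 0.0615 (H1299 and THP-1) to 0.217 (A549 and H1299), and Spearman's rho from 0.0355 to 0.210.

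**Figure D3:**
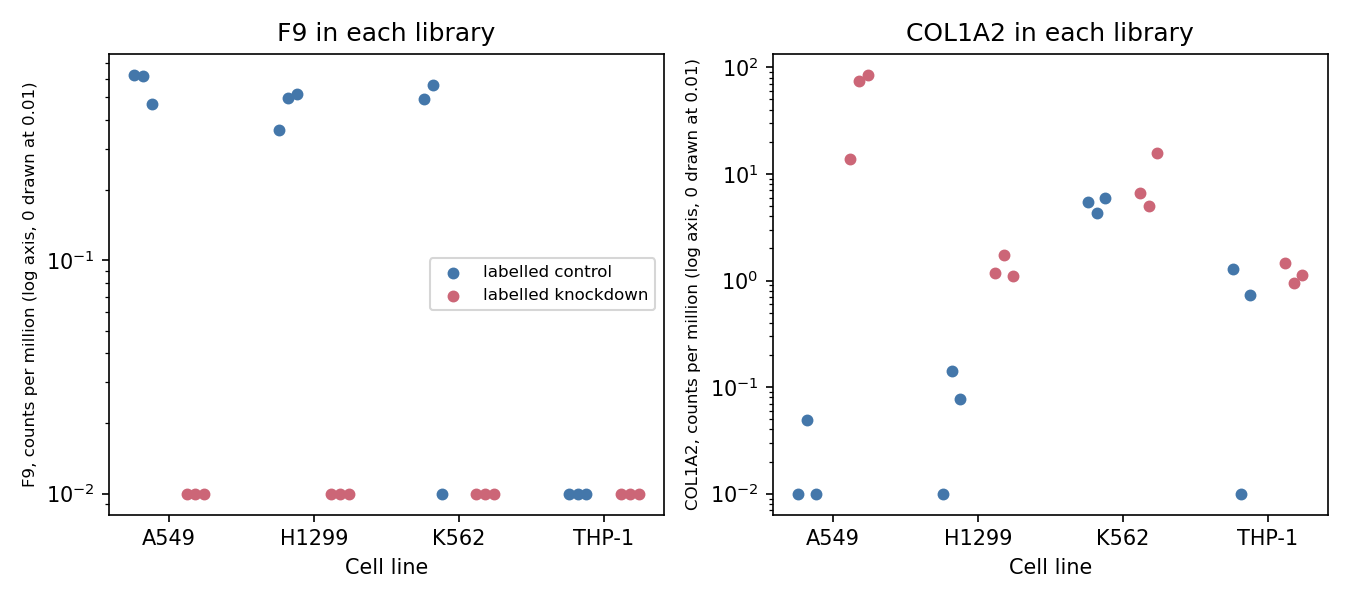
F9 (left) and COL1A2 (right) in each of the 24 libraries, in CPM of total estimated counts on log axes with 0 drawn at 0.01. F9 was above 0 in 8 libraries, all labelled control (3 of A549, 3 of H1299 and 2 of K562), and COL1A2 was at 13.8, 74.7 and 85.0 CPM in the 3 A549 libraries labelled knockdown.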

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

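The tests of scaling and exchanged labels for CBX7, of a cell response for the A549 matrix genes, and of the respiratory chain length trend, the THP-1 quality axis and the library sets for H1299 were chosen after the result was seen. The fibroblast and ribosomal length tests were written before their results, but for patterns already seen in the data. The split tests were written before their results.

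CBX7 was higher in every library labelled knockdown. Scaling of the counts is argued against, since the smallest log2 fold change over lines and the settings run for CBX7 was 1.05 (SE 0.11). Arm labels exchanged in all 4 lines, or forced expression of CBX7, may each explain the direction, and they cannot be told apart, because CBX7 was higher in all 3 libraries labelled knockdown in 4 of 4 lines and both predict that. The titles of both arms contain CBX7, so they do not settle it.

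The matrix genes of A549 were much higher in knockdown replicates 2 and 3 than in replicate 1. Reads from fibroblasts may explain this: the median log2 ratio of replicates 2 and 3 to replicate 1 was 0.87 (quartiles 0.52 to 1.60) for fixed fibroblast markers low in the controls, against 2.50 for COL1A2, COL6A3 and DCN. That met the bound set beforehand against fibroblasts, but it rested on 4 markers near the floor; of 24 markers 14 were expressed in A549 controls and 12 were also in the mesenchymal list. A response of the A549 cells is also open: the same 2.50 lay outside the middle 95% (-0.83 to 1.26) of 501 other genes called at least 2-fold higher, but it came from 3 genes chosen for the pattern. Single genes, chosen after their values were seen, went both ways (CPM of total counts, knockdown replicates 1, 2 and 3). COL1A1 was at 42.5, 130.5 and 143.7. PDGFRA was at 3.039, 8.755 and 11.97, PDGFRB at 0.5768, 4.394 and 3.734 and LOX at 2.996, 9.268 and 9.385. THY1 was at 13.31, 15.77 and 16.68, POSTN at 0.3798, 0.6542 and 0.4481 and TBX5 at 0.2391, 0.3053 and 0.361. COL5A2 was at 481.8 to 500.7 in all 6 A549 libraries, a level at which a few added reads would not show. In K562 COL1A1 was at 0.508, 0.399 and 2.72 in the controls and 10.4, 7.75 and 22.6 in the libraries labelled knockdown.

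Ribosomal protein and respiratory chain genes were lower in H1299 libraries labelled knockdown. Removing the trend with transcript length, 3' UTR length and GC content moved the ribosomal median from -0.93 to -0.59 (quartiles -0.79 to -0.41) and the respiratory median from -0.64 to -0.28 (quartiles -0.59 to -0.12), so the trend may hold part of both, and how much cannot be told apart from an effect on these genes, as quartiles reach past the limit of 0.5 times the first median. A difference in library quality is a candidate explanation, since the H1299 change was correlated at -0.37 across 13239 genes, which are not independent replicates, with the difference of THP-1 knockdown replicate 2 from replicates 1 and 3, against -0.09 in A549 and -0.01 in K562. Clotting gene reads in both arms, the sign set down against a difference between library sets, were found, as all 3 H1299 libraries labelled knockdown held reads of F11 or F5 (at most 0.1045 and 0.0572 CPM). They do not decide, because for 0 of 7 clotting and plasma protein genes, chosen after their values were seen, did the arms overlap (F11 was at 0.343 CPM or more and F5 at 3.39 CPM or more in the controls), so library set and label cannot be told apart.

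Within a line the 10 splits of 6 libraries are too few for a share under 0.05: the real split called 8324 genes in A549, 10075 in H1299, 7834 in K562 and 1458 in THP-1, in each case 1 of 10 splits with as many. The highest other split called 3, 0, 2 and 1 (150, 96, 132 and 616 at an unadjusted p under 0.05, edgeR). For the average effect over lines, 1 of 40 splits, the real one, called as many as the real 8420, the highest other calling 7172. A chance division of these libraries is argued against. A chance difference between cultures is not, since the labels do not say that the replicates were separate cultures. For the difference between lines, 2 of 40 did, with 10898 in the real split and 11238 in the other, so chance was not excluded by this count; that split kept or exchanged the true arms in all 4 lines. In the 21 splits that kept no line's arms, at most 10 genes were called.

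Gene lists are given next because a camera test of the difference between lines was past an adjusted p of 0.05, as in 81 of 174 tests; 36 were past with an estimated correlation and 45 were not. For each of the 24 lists concerned, the pair of lines with the smallest adjusted p is given, as the difference in median log2 fold change. The other 24 tests that held and 33 that did not are other pairs of these lists. The H1299 trend with transcript length was not removed for these tests. For 12 lists the pair given also passed with an estimated correlation. It was, for A549 minus THP-1, -1.17 in S phase, -1.89 in G2 and mitosis, 0.36 in p53 targets, -0.74 in NRF2 targets and -0.63 in ERK feedback genes. For K562 minus THP-1 they were -1.19 in interferon genes, -1.41 in cholesterol synthesis, -0.38 in autophagy and lysosome genes and -0.71 in heat shock proteins. For A549 minus K562 they were -2.41 in ATF4 response genes and 0.86 in NF-kappaB targets, and for H1299 minus THP-1 -0.68 in ribosome biogenesis. For the other 12 lists the pair given was lost with an estimated correlation. It was, for K562 minus THP-1, -0.74 in secretory senescence genes (adjusted p = 0.169), -0.60 in fatty acid synthesis (0.0537), 0.86 in Wnt targets (0.170) and -0.63 in immediate early genes (0.196). For A549 minus H1299 they were 0.62 in mesenchymal genes (0.490), 0.76 in TGF-beta targets (0.203) and 1.07 in ribosomal proteins (0.163). For H1299 minus THP-1 they were -0.44 in endoplasmic reticulum chaperones (0.143), -0.69 in the respiratory chain (0.314) and -0.61 in CDK inhibitors (0.0753). For A549 minus K562 it was 0.90 in monocyte genes (0.143) and for H1299 minus K562 0.34 in hypoxia genes (0.0753).

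Of 106 genes called the same way in all 4 lines, 88 differed in size between lines by the interaction test of edgeR. Among the 20 of them that the naming rule took, 14 did. The H1299 trend with transcript length was not removed for this test. The adjusted p was 1.10e-12 for CBX7, 2.04e-09 for RECQL4, 1.57e-08 for SRRT, 3.80e-07 for TELO2, 8.38e-07 for MRAS, 5.50e-06 for ARHGAP33, 7.95e-06 for GBP1, 1.11e-05 for RHOT2, 0.000268 for SARS2, 0.000620 for CPS1, 0.00181 for CHI3L1, 0.00260 for GDF15, 0.0114 for TMTC1 and 0.0150 for RASGRP3. CHI3L1 lost its H1299 call without knockdown replicate 2 (adjusted p = 0.0621) and RASGRP3 without knockdown replicate 1 (0.0520). In CPM of total counts, CHI3L1 was at 1297 to 1437 in THP-1 controls and 3536 to 3867 in THP-1 libraries labelled knockdown. In the other lines it was near the floor, at most 0.333 CPM in controls and 0.386 to 2.39 CPM in libraries labelled knockdown. TMTC1 lost its A549 call without control replicates 1, 2 or 3 (0.0535, 0.0689 and 0.0676) and its K562 call without control replicates 1 or 2 (0.0810 and 0.0637) or knockdown replicates 1 or 3 (0.108 and 0.1004). It also lost both calls in the lone-library comparisons, with A549 knockdown replicate 1 alone (0.202) and K562 control replicate 3 alone (0.225). In THP-1 the calls of RECQL4, SRRT, TELO2, RHOT2, SARS2, CPS1, GDF15 and TMTC1 ended without at least 1 of control replicates 1, 2 and 3 and knockdown replicates 1 and 3, at adjusted p of 0.0569 to 0.150.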

How the results depend on the processing

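Counts divided by 4, K562 control replicate 3 alone and A549 knockdown replicate 1 alone were chosen after seeing the data. CBX7 kept its direction and call in all settings run for it (log2 fold change 1.05 to 3.73, highest adjusted p 0.0167). Leaving out single libraries gave 3.03 to 3.14 in A549, 3.60 to 3.64 in H1299, 1.48 to 1.57 in K562 and 1.12 to 1.29 in THP-1. At a 2-fold limit, higher and lower calls were 747 and 463 in A549, 1303 and 746 in H1299, 1080 and 351 in K562 and 343 and 70 in THP-1, since fewer genes can pass. With all 24 libraries in one fit, 2914 genes were higher and 2750 lower in A549, and 2044 were higher and 1714 lower in THP-1; DESeq2's Wald test called 916 lower in THP-1; the cause was not tested. Without single THP-1 libraries the counts ran from 392 (control replicate 3) to 1738 (knockdown replicate 2) higher and from 167 (control replicate 2) to 1586 (knockdown replicate 2) lower. Elsewhere they ran from 3561 to 3944 higher and 3845 to 4247 lower in A549, 4637 to 4775 and 4959 to 5034 in H1299, and 3533 to 3826 and 3422 to 3699 in K562. With an estimated correlation 4 lists passed in A549, 0 in H1299 (6 at an unadjusted p under 0.05), 1 in K562 and 1 in THP-1. The fry test, which asks another question, called 33, 35, 32 and 27 in A549, H1299, K562 and THP-1. Of 21 THP-1 lists past camera, 19 passed fry. Ribosomal proteins (fry adjusted p = 0.354) and heat shock proteins (0.105) did not. Genes called the same way in all 4 lines were 106, and 18 at an adjusted p under 0.01, 179 with DESeq2 and 2 at a 2-fold limit. SREBF1 in H1299 changed sign under limma on log2(FPKM + 1) (0.0455) and log2(FPKM + 0.1) (0.0459), neither past the threshold; the cause was not tested. Among named genes, 98 of 1512 results were weaker in A549, 20 of 917 in H1299, 56 of 1168 in K562 and 250 of 1108 in THP-1. Those results and the CBX7 range leave out the fits without a filter, with the 1 CPM filter and of all 24 libraries together. Counts divided by 4 gave 4089 higher and 4209 lower in A549, 4897 and 5087 in H1299, 3989 and 3768 in K562 and 931 and 619 in THP-1. With A549 knockdown replicate 1 alone, 3252 genes were higher and 3905 lower, 17 of 19 list calls held and 12 of 119 calls of named genes ended, and with K562 control replicate 3 alone 12 of 12 held and 14 of 93 ended. Most 1.5-fold changes in THP-1 were missed in simulations with 200 changed genes. More genes than that were called in the data, so recovery there may differ.

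Replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.0449 to 0.0398, and in 3 of 12 comparisons the library correlated best with its own number. With the replicate block, 3984 genes were higher and 4334 lower in A549, 4703 and 5069 in H1299, 3680 and 3575 in K562 and 754 and 445 in THP-1.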

Other observations

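The gene groups below were fixed before the data were examined, and no explanation was tested for them. In A549, 13 of 21 TGF-beta targets rose and 3 fell (15 and 3 adjusted over the list alone), and 16 rose and 3 fell of 26 YAP targets (16 and 3), with CTGF, a secreted matricellular protein, higher (0.72 ± 0.06). Of 24 endoplasmic reticulum chaperones 14 rose (14), with DNAJB9 higher (1.34 ± 0.06). Adjusted p from camera was 0.000289, 0.00210 and 0.000404. It became adjusted p = 0.0770 for each with an estimated correlation. COL1A1 among the TGF-beta targets (18.6 ± 0.38 and 103.1 ± 53.9 CPM), F3 among the YAP targets (2.75 ± 0.60 and 16.9 ± 10.02 CPM) and IGFBP5 among the secretory senescence genes shared the pattern of the matrix genes, at least 2-fold higher in knockdown replicates 2 and 3 than in replicate 1. The calls of COL1A1 and F3 ended without any 1 control library, knockdown replicate 2 or knockdown replicate 3 (adjusted p of 0.0568 to 0.0749 and 0.0879 to 0.108). Among genes called higher, such a difference was seen in 1 of 13 TGF-beta targets, 1 of 16 YAP targets and 2 of 17 secretory senescence genes. It was seen in 1 of 7 monocyte genes (CD4), 6 of 23 mesenchymal genes and 87 of all 4069 genes. With knockdown replicate 1 alone the calls of the TGF-beta and YAP lists held. Of 42 interferon genes 21 rose and 5 fell (21 and 5), with OAS3 at -0.87 among those that fell (adjusted p = 0.00608, adjusted p = 0.0777 with an estimated correlation). Of 32 autophagy and lysosome genes 16 rose and 8 fell (16 and 9), with WIPI1 at 0.88 and GLA at -0.91 (adjusted p = 0.0258, adjusted p = 0.227 with an estimated correlation). Of 14 neural genes 5 rose and 1 fell (5 and 1), with CHGB, a secretory granule protein, from 22.2 ± 0.99 to 94.5 ± 2.39 CPM (adjusted p = 0.0242, adjusted p = 0.143 with an estimated correlation). Secretory senescence genes (17 higher and 7 lower of 35, 17 and 7) had adjusted p = 0.0455, which was 0.0555 without knockdown replicate 3 and 0.0537 with knockdown replicate 1 alone. Monocyte genes (7 higher of 22, 6) had adjusted p = 0.0258, which was 0.0525 without knockdown replicate 2 and 0.0604 with knockdown replicate 1 alone, and the 2 lists had adjusted p = 0.301 and 0.148 with an estimated correlation. The numbers in brackets are those adjusted over the list alone.

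In K562, 10 of 22 YAP targets rose and 1 fell (10 and 1 adjusted over the list alone), 8 of 12 Wnt targets rose and 1 fell (8 and 1), with LEF1 higher (0.99 ± 0.14) and RNF43 lower (-0.74). Of 32 autophagy and lysosome genes 7 rose and 16 fell (7 and 16). The set test by camera gave adjusted p = 0.0224, 0.0415 (0.0554 without knockdown replicate 3) and 0.0360, and adjusted p = 0.414, 0.351 and 0.516 with an estimated correlation. In THP-1, 9 of 32 autophagy and lysosome genes rose and 1 fell (11 and 1), with CTSL, a lysosomal protease, at 1.35 ± 0.10. Among fatty acid synthesis genes 9 of 17 rose (9), and 5 of 21 TGF-beta targets (8), with TGFBI at 0.83 ± 0.08. The camera adjusted p was 0.000394, 8.36e-05 and 0.000121, and adjusted p = 0.193, 0.275 and 0.275 with an estimated correlation. Of 26 immediate early genes 6 rose and 1 fell (9 and 3), with ATF3 at 1.59 ± 0.18 (adjusted p = 0.0147, adjusted p = 0.370 with an estimated correlation). Of 35 mesenchymal genes 3 rose (5), FAP among them (adjusted p = 0.00712, adjusted p = 0.403 with an estimated correlation). Genes of G2 and mitosis had a median of 0.13 in THP-1 (adjusted p = 0.00699, adjusted p = 0.275 with an estimated correlation), with 0 of 55 called by edgeR, over all genes or adjusted over the list alone, 15 higher at an unadjusted p under 0.05 and 8 called higher by DESeq2. With the trend in length, 3' UTR length and GC content removed their median was 0.01 (quartiles -0.08 to 0.15). The mean level of other genes was removed with it, so that move is not assigned to length or GC content. In THP-1 ribosome biogenesis genes had a median of -0.14 (adjusted p = 0.00679, adjusted p = 0.190 with an estimated correlation).

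Further THP-1 list calls rested on single libraries. Hypoxia genes (2 higher and 5 lower of 34, 2 and 8 adjusted over the list alone) had adjusted p = 0.0317, which was 0.0551 without knockdown replicate 1 and 0.0840 without knockdown replicate 3. Wnt targets (3 higher of 15, 4) had 0.0424, which was 0.0852 and 0.0650 without control replicates 2 and 3 and 0.0775 and 0.117 without knockdown replicates 1 and 3. Without knockdown replicate 2 the adjusted p of secretory senescence genes went from 0.0157 to 0.1003. That of heat shock proteins then went from 0.0191 to 0.177 (0.0545 without control replicate 3). Their median of 0.14 was 0.03 with the length and GC trend and the mean level of other genes removed. The adjusted p of granule protein genes went from 0.0157 to 0.3075 without knockdown replicate 2. With an estimated correlation the adjusted p of these lists was 0.229, 0.403, 0.227, 0.466 and 0.370. Mesenchymal genes in H1299 had a median of 0.12 and a mean of 0.32 while the test pointed down, and monocyte genes in K562 a median of -0.30 and a mean of 0.05 with a test pointing down, none past the threshold.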
